A study of Mus musculus with 18 samples.

How the data were processed

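RNA bound to tagged ribosomes (Ribo-TRAP, which pulls down the transcripts being translated in a labelled cell type) was measured by RNA sequencing in 18 mouse samples. Per the labels, 4 wild-type (WT) and 4 knockout (KO) samples for the RNA-binding protein RBM20 came from parvalbumin-positive (PV) neurons of the neocortex, and 5 WT and 5 KO samples from glutamatergic neurons of the olfactory bulb (OB). Each sample took its group from its title. Per the labels, polyadenylated RNA was extracted with an RNeasy column kit and libraries were made with a SMARTER mRNA-Seq kit. Nothing in the labels says whether samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

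Gene levels were the FPKM values the authors deposited for every sample, in one table per neuron type, with gene models and identifiers of FAST DB per the file headers. Exon levels were the RPKM values the authors deposited per exon part, in one table per neuron type, with cells left blank below a minimum that lay between 0.436 and 0.598 in the OB samples and between 0.596 and 0.688 in the PV samples. The submitters' processing notes name the genome build mm10, STAR 2.4.0, featureCounts, SAMtools, Picard, FastQC, DESeq2 and R 3.5.3, without saying which step each was used for. The authors' deposited tables of KO against WT hold a signed fold change (written as a score, negative where KO is lower), a p-value and, for genes, an adjusted p-value, per the file headers. Their exon p-values are not adjusted, per the file headers. Whether counting used the strand is not given in the sources used here, so levels of overlapping or antisense genes are uncertain.

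The columns of the PV gene and exon tables and of the OB exon table were matched to samples by the genotype and number in their names. The OB gene table numbers its WT columns 1, 2, 4, 5 and 6, which are not the sample numbers of the labels, so those columns were used as WT replicates without a sample number and are called OB WT 1, 2, 4, 5 and 6 by column. All per-sample columns were used (0 were left out). Tables of the neuron types were handled separately, and no level was tested across them.

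FPKM tables hold no counts. Low FPKM values of a gene move in steps that differ between samples, and the ratio of these steps gives the depth relative to the mean of the table: 0.739 to 1.16 in OB and 0.896 to 1.13 in PV. After scaling by it, 52.2% of low values in OB and 48.8% in PV were whole multiples of the lowest value of their gene, against 2.67% and 1.67% without scaling. Multiplied by summed exon length, at most 7.17% and 2.63% were whole multiples of a common step (median over the steps tried 1.71% and 1.79%). The value of a single read was therefore not set for each gene, and no counting interval or detection floor is given. OB KO 1 was the shallowest by this measure.

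Gene tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a mean trend) on log2(FPKM + 0.5), over genes with a mean FPKM of at least 0.5, KO against WT within a table, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. All fold changes are on the log2(value + 0.5) scale, KO minus WT. Exon tests used limma's diffSplice on log2(RPKM + 0.5) for exon parts with a mean RPKM of at least 0.5. A tested part was listed in every sample of at least 1 genotype, in a gene with several parts listed in every sample. A part passed at an adjusted p under 0.05 and a change of at least 1 (log2) relative to the other parts of its gene. Blank cells were set to the lowest listed value of the sample, and made up 1.15% of the tested cells in OB and 0.552% in PV. They were more common among the calls: 13 of 37 called parts in OB and 4 of 8 in PV held blank cells. The difference of the KO effects between neuron types was an interaction contrast in limma over the genes tested in both tables, with all 18 samples. Single values were compared with exact two-sided permutation tests, and shares of genes with Fisher's exact test (two-sided).

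Gene lists, 26 in all, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, and again with an estimated correlation and with fry, which asks whether a list moves on balance one way without comparing it with other genes. The lists covered synaptic, ion channel, axon guidance, ribosomal, oxidative phosphorylation, stress, immediate early and splicing genes, RBM20 targets known from heart, and markers of mitral and tufted cells, granule and periglomerular cells, olfactory sensory neurons, PV and other cortical interneurons, cortical excitatory neurons, astrocytes, oligodendrocytes and their precursors, microglia, and endothelial and mural cells. Endothelial and mural markers (3 measured in OB and 4 in PV), oligodendrocyte precursor markers (2 and 4) and sex-linked genes (4 and 4) had too few measured members to test in either table, and mitral and tufted markers (4) and olfactory sensory neuron markers (4) too few in PV. Some markers stand in more than one list, such as Gad1 and Reln. Long genes spanned at least 100 kb in the coordinates of the files (mm10), which give a span for every gene tested.

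The samples of each group, the tests, the filters, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule named, per neuron type, Rbm20, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean FPKM of at least 1 in a genotype and no overlap between genotypes. Where fewer than 10 genes passed, it named the 10 with the smallest p. It also named the 3 members of each list with the smallest p among those that passed, the measured cardiac RBM20 targets, the 5 genes with the smallest p for the difference between neuron types, and the 10 exon parts with the largest relative change that passed without overlap. Genes without an official name were counted and not named.

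Where WT and KO share replicate numbers, the numbers were checked for pairing by the correlation of the deviations from the group means. All 4 PV pairs deviated together (0.186 to 0.262 over genes and 0.118 to 0.183 over exon parts), so the PV numbers were taken to pair the samples, as a hint from the data, and a fit with the number as a block was run. The OB gene columns that share a number (1, 2, 4 and 5) also deviated together (0.197 to 0.260). The WT numbers among them are not sample numbers, so a fit with these column numbers as a block was added after the data were seen. The OB exon pairs ranged from -0.0347 to 0.279 and were not taken as pairs. Correlations between differently numbered samples were not taken for comparison. Samples numbered 1 and 2 stood apart from later ones in both neuron types, which could make same-numbered samples deviate together. Pairing beyond that was therefore not shown.

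The tests of genes, gene lists, long genes, exons and the difference between neuron types were tried on simulated data made from the real levels with known changes. In OB the gene test recovered 26.9% of simulated changes of 0.5 (log2), 86.6% of changes of 1 and 98.5% of changes of 2. In PV it recovered 67.2%, 94.0% and 100% of them. For the difference between neuron types the shares were 25.0%, 72.7% and 97.5%. The exon test recovered 66.0% of changes of 1 in OB and 90.0% in PV, and it also called parts of unchanged genes at an adjusted p under 0.05: 38 of 211 calls in OB and 54 of 266 in PV. With the size threshold, 12 of 148 calls in OB and 3 of 159 in PV were false. Simulated noise was independent between samples and held no column batch, and the spread of each exon part was averaged with that of its gene. The false shares were therefore not shown to hold for the real samples. There, other splits of the samples gave up to 39 exon calls in OB and 11 in PV.

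Alternatives tried were other pseudocounts (0.1 and 1), filters and scalings (median centring, quantile), sample weights, robust shrinkage, a fold change minimum, sex as a covariate in OB, leaving out each replicate in turn, other length thresholds, the replicate block, and other exon models. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Raw reads, read counts and a genome sequence were not used here.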

Results

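Ribosome-bound RNA was compared between RBM20 WT and KO mice in a pair of neuron types, to ask which transcripts and which exons depend on RBM20, a splicing factor best known from heart muscle, in neurons. The OB table held 56624 gene models in 5 WT and 5 KO samples, and the PV data held 56637 in 4 WT and 4 KO samples. Summed FPKM was 492208 to 537629 in the OB KO samples and 437468 to 488953 in the OB WT samples, without overlap. In PV it ranged from 424202 to 442366. Genes with a level above 0 numbered 19489 to 21792 in the OB KO samples and 23097 to 24952 in the OB WT samples, without overlap, and 22807 to 24730 in the PV samples. Within OB, samples numbered 1 and 2 stood apart from the later ones: 3113 of 13343 tested genes differed between these sets in limma, and OB WT 1 and OB WT 2 lay farthest out on the first principal component, which held 42.1% of the variance. In PV, 390 of 13206 genes differed between samples numbered 1 and 2 and those numbered 3 and 4. The labels give no batch, so these sets are called column batches, and both hold both genotypes.

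The pull-downs held the transcripts of the intended neuron types. In OB WT samples the vesicular glutamate transporter Slc17a7 was at 1510 ± 289 FPKM (SD, n = 5), and the mitral and tufted cell genes Cdhr1 at 781 ± 88.5 and Eomes at 326 ± 68.1, against 7.27 ± 3.41 for Gad1, which makes the inhibitory transmitter GABA. In PV WT samples Gad1 was at 1506 ± 169 FPKM (SD, n = 4), the fast potassium channel gene Kcnc1 at 490 ± 29.5, Slc32a1 at 264 ± 25.2 and Pvalb at 930 ± 473, against 19.4 ± 2.63 for Slc17a7. Markers of other interneurons were present in PV, with Npy at 176 ± 66.8 and Sst at 45.4 ± 9.76.

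Rbm20 (chr19:53677305-53867080, mm10) fell in the KO samples of both neuron types. In OB it fell from 8.81 ± 2.86 FPKM (SD, n = 5) in WT to 0.351 ± 0.0352 (n = 5) in KO, 3.99% of the WT level. The log2 fold change was -3.40 (SE 0.18, limma adjusted p = 5.78e-06, exact permutation p = 0.00794 over 252 arrangements). In PV it fell from 3.75 ± 0.425 (n = 4) to 0.593 ± 0.179 (n = 4), 15.8% of the WT level, a log2 fold change of -1.97 (SE 0.13, limma adjusted p = 7.39e-05, exact permutation p = 0.0286 over 70 arrangements). Within column batches the log2 change was -3.91 (samples 1 and 2) and -3.06 (later) in OB, and -1.80 and -2.14 in PV. In the OB exon table, 14 of 15 exons of Rbm20 were listed in all 5 WT samples and none in any KO sample, with exon 12 listed in 1 WT sample. In PV, 13 exons were listed in all 4 WT samples and in at most 2 of the 4 KO samples, the highest KO value being 1.64 RPKM for exon 10. Genes within 10 Mb of Rbm20 were not called more often than others in OB (6 of 120, Fisher exact p = 0.477), and none of them was called in PV.

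**Figure D1:**
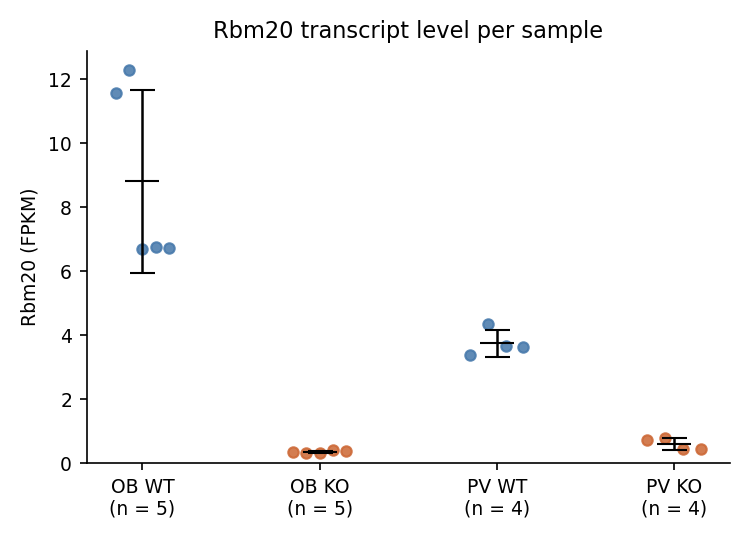
Rbm20 level in FPKM for each WT and KO sample of the OB and PV tables, with the group mean and SD. KO samples lie between 0.314 and 0.399 in OB and between 0.440 and 0.780 in PV, below every WT sample of the same table.

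In OB KO, 441 genes rose and 529 fell. The dermatan and chondroitin sulfate-modifying enzyme Ust rose most among the named genes, from 7.39 ± 2.16 to 26.7 ± 4.16 FPKM (SD, n = 5 each), a log2 change of 1.81 (SE 0.18, limma adjusted p = 0.00207). Also named as rising were Rec114 (1.70), Zc3h12d (1.55), the class I antigen subunit B2m (1.21), the chemokine Ccl17 (1.21), Tpm2 (1.21), Adat2 (1.12), Cytip (1.03), Sdf2l1 (0.98) and Hdhd3 (0.97). Besides Rbm20, the phospholipase Pla2g4e fell most among the named genes, from 7.08 ± 5.32 to 0.836 ± 0.359 FPKM. Its log2 change was -2.14 (SE 0.51, limma adjusted p = 0.0406). It was followed by Prrc2c (-1.52), the GABA receptor subunit Gabra2 (-1.51), the AMPA receptor partner Cacng2 (-1.46), the spectrin Sptbn2 (-1.41), the membrane adaptor Ank3 (-1.38), the presynaptic scaffold Pclo (-1.36), Mycbp2 (-1.33) and Tnrc6c (-1.32). The naming rule admitted only genes without overlap between genotypes. With shared column numbers as a block, a setting chosen after the data were seen, Ccl17 (adjusted p = 0.0582) and Pla2g4e (adjusted p = 0.0572) no longer passed.

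Limma called 970 of 13343 genes in OB, 441 higher and 529 lower in KO, with 118 calls in genes without an official name. Changes of at least 1.5-fold among the calls numbered 493, of which 107 were higher and 386 lower. WT and KO did not overlap in 619 of the called genes, and in 7.87% of the tested genes against 0.794% by chance. At an unadjusted p under 0.05 there were 4296 genes. The median log2 change of all genes was -0.06, and 0.07 after each sample was centred on its median, which gave 1095 calls, of which 731 (66.8%) were higher, against 45.5% without centring. The number of calls hung on most single libraries: it was 905 without OB WT 5, 63 without OB KO 1, 3400 without OB KO 2, 16 without OB KO 3, 6 without OB KO 4, 4 without OB KO 5, 32 without OB WT 1, 23 without OB WT 2, 48 without OB WT 4 and 5 without OB WT 6. Genes at p under 0.05 ranged from 3219 to 5396 in those fits. Within column batches, 3276 genes were called in the later samples (3 per genotype) and 1 in samples 1 and 2 (2 per genotype, 2970 at p under 0.05). With the batch as a covariate 3982 were called, which held all 970, and with the column numbers shared by WT and KO as a replicate block 1531, 531 higher and 1000 lower, which held 741 of the 970.

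Cytosolic ribosomal protein genes passed camera upward in OB KO. All 76 measured members had a positive change (median 0.46), 17 rose and 59 did not pass, and 69 rose when adjusted over the list alone. Rpl3 rose from 156 ± 27.5 to 264 ± 29.1 FPKM (log2 0.77), Fau by 0.57 and Rpl11 by 0.51. The camera adjusted p was 1.89e-24, and the adjusted p = 0.384 with an estimated correlation. Genes of oxidative phosphorylation, which makes ATP in mitochondria, had a median of 0.46: 32 of 75 rose, 0 fell in limma, and 67 rose when adjusted over the list alone. Atp5j2 rose from 628 ± 70.9 to 995 ± 106 FPKM (log2 0.67), Cox5a by 0.57 and Ndufa5 by 0.55 (camera adjusted p = 5.98e-25, adjusted p = 0.384 with an estimated correlation). Of 27 stress response genes, 9 rose and 11 when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.000256, adjusted p = 0.384 with an estimated correlation). Those named by the rule act in the endoplasmic reticulum: the disulfide isomerase Pdia6 rose by 0.56, Manf by 0.63 and Sdf2l1 by 0.98. KO samples with these higher levels also had fewer genes above 0 and lower oligodendrocyte transcripts (median -0.44). Genes spanning at least 100 kb were 0 of the 76 ribosomal, 1 of the 75 oxidative phosphorylation and 0 of the 27 stress response genes. OB changes followed summed exon length across genes (rho = -0.469), so these rises may in part follow length.

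In OB KO, 4 lists of synaptic and axon guidance genes passed camera downward, although most of their members did not pass singly. Of 77 synaptic adhesion genes, 10 fell and 24 when adjusted over the list alone, with a median of -0.41 (camera adjusted p = 4.53e-09), among them Dscaml1 (-1.07), Flrt1 (-0.93) and the latrophilin Adgrl1 (-0.88). Of 51 glutamate receptor and postsynaptic density genes, 7 fell and 18 when adjusted over the list alone (median -0.42, adjusted p = 6.97e-07), including the scaffolds Shank2 (-1.19) and Shank1 (-0.58) and the AMPA receptor partner Cacng4 (-0.79). Of 45 presynaptic release genes, 7 fell and 13 when adjusted over the list alone (median -0.31, adjusted p = 0.000239). Besides Pclo these included its fellow scaffold Bsn (from 19.1 ± 2.94 to 8.78 ± 3.46 FPKM, log2 -1.13) and the vesicle priming factor Unc13a (-0.98). Of 41 axon guidance genes, 4 fell and 16 when adjusted over the list alone (median -0.52, adjusted p = 3.74e-07), such as Plxna1 (-0.82), Sema5b (-0.67) and Sema4d (-0.61). All 4 lists had an adjusted p = 0.384 with an estimated correlation. Genes spanning at least 100 kb made up 53 of the 77, 30 of the 51, 22 of the 45 and 34 of the 41 members, in that order. OB changes followed summed exon length across genes (rho = -0.469), so these shifts may in part follow length. The 4 lists kept their calls with that trend removed, a setting chosen after the data were seen. Oligodendrocyte transcripts and Gad1 were lower in the same KO samples.

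Ion channel lists passed camera downward as well, with most members not passing singly. Of 47 calcium channel and calcium handling genes, 6 fell, and adjusted over the list alone 20 fell and 3 rose (median -0.40, camera adjusted p = 0.000167). The T-type channels Cacna1h (-1.09) and Cacna1g (-0.82) and the calcium pump Atp2b4 (-1.08) were the named ones. Of 48 potassium channel genes, 5 fell and 12 when adjusted over the list alone (median -0.32, adjusted p = 7.20e-05), with Kcna2 at -0.98, Kcnb1 at -0.88 and Kcnc3 at -0.59. Of 15 genes for sodium channels and their anchors, 4 fell and 7 when adjusted over the list alone (median -0.58, adjusted p = 0.0194). The named members Ank3 (-1.38), Ank2 (-1.32) and Sptbn4 (-0.65) code for membrane scaffolds and not for channels. All 3 lists had an adjusted p = 0.384 with an estimated correlation. The sodium channel list no longer passed once the trend on summed exon length was removed, a setting chosen after the data were seen (adjusted p = 0.107). Genes spanning at least 100 kb made up 27 of the 47, 20 of the 48 and 10 of the 15 members, so these shifts may in part follow length too. Oligodendrocyte transcripts and Gad1 were lower in the same KO samples here too.

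Among markers of other cells, the oligodendrocyte list passed camera downward in OB KO. All 9 measured had negative changes (median -0.44), 3 fell and 6 when adjusted over the list alone: the myelin genes Plp1 (from 9.41 ± 3.12 to 4.44 ± 0.792 FPKM), Mag (-0.68) and Mbp (-0.58). The camera adjusted p was 0.000416, and the adjusted p = 0.137 with an estimated correlation. The lists of the intended neurons and of other cells did not pass camera. Mitral and tufted markers had a median of 0.01 and a mean of -0.01, and Ebf3 fell (camera adjusted p = 0.506). Granule and periglomerular markers were at -0.23 (0.129) and PV interneuron markers at -0.22 (0.129), and Gad1, which stands in both, fell by 0.96 on the log2 scale. Other cortical interneuron markers were at -0.40 (0.506, Sst fell), cortical excitatory markers at -0.51 (0.157, Cux2 fell), astrocyte markers at -0.31 (0.15, Atp1a2 fell) and olfactory sensory neuron markers at -0.55 (0.0940). With shared column numbers as a replicate block, the olfactory sensory neuron list passed (adjusted p = 0.00527, adjusted p = 0.464 with an estimated correlation), and Ebf3 (adjusted p = 0.0542) and Sst (adjusted p = 0.0574) no longer did. Microglial markers had a median of -0.04, a mean of 0.00 and an upward test direction (0.706). With fry, which does not compare a list with other genes, some of these lists passed, each with a negative median. They were astrocyte (fry adjusted p = 0.0267), granule and periglomerular (0.0268), PV interneuron (0.0223) and other cortical interneuron markers (0.00258). Cortical excitatory (0.0529), olfactory sensory neuron (0.227), mitral and tufted (0.96) and microglial markers (0.963) did not. All 11 olfactory sensory neuron markers had negative changes.

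Of the remaining lists, GABA and glycine synapse genes did not pass in OB (median -0.27, camera adjusted p = 0.126), although 4 of 25 fell, among them Gabra2, Iqsec3 (-0.75) and the GABA transporter Slc6a11 (-0.63). Splicing factor genes did not pass either (median -0.20, 0.0974), with 5 of 58 falling: the RNA-binding proteins Elavl3 (-1.14) and Celf4 (-0.66), the microexon regulator Srrm4 (-0.65) and 2 others. Immediate early genes had a median of -0.14 (0.706). Genes known as RBM20 targets in heart had a median of -0.34 over 19 members, of which Dst fell (from 1.40 ± 0.935 to 0.294 ± 0.103 FPKM, log2 -1.13) and 2 fell when adjusted over the list alone. Their camera adjusted p was 0.0251, and the adjusted p = 0.394 with an estimated correlation. This list no longer passed without OB KO 2 (0.0520), without OB KO 5 (0.0674), without OB WT 1 and 2 (0.0697) or with the exon-length trend removed (0.677). The other measured members with a mean FPKM of at least 1 did not pass, and ranged from -0.71 for Ktn1 to 0.21 for Pdlim3.

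In all, 12 of 23 lists passed camera in OB, 3 upward and 9 downward, and all 12 kept their direction with quantile scaling. With an estimated correlation 0 passed (2 at p under 0.05, lowest adjusted p = 0.137), and with fry 18 passed. The authors' deposited table for OB called 1483 of 13604 genes at an adjusted p under 0.05, 774 higher and 709 lower. Of these, 858 were also called here, all with the same sign, where 106 would be shared by independent lists of these sizes. Both sets of calls come from the same samples, so this overlap is not independent support. Over the 13300 genes in both, log2 changes of the authors' deposited table and of limma correlated at r = 0.951 across genes.

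**Figure D2:**
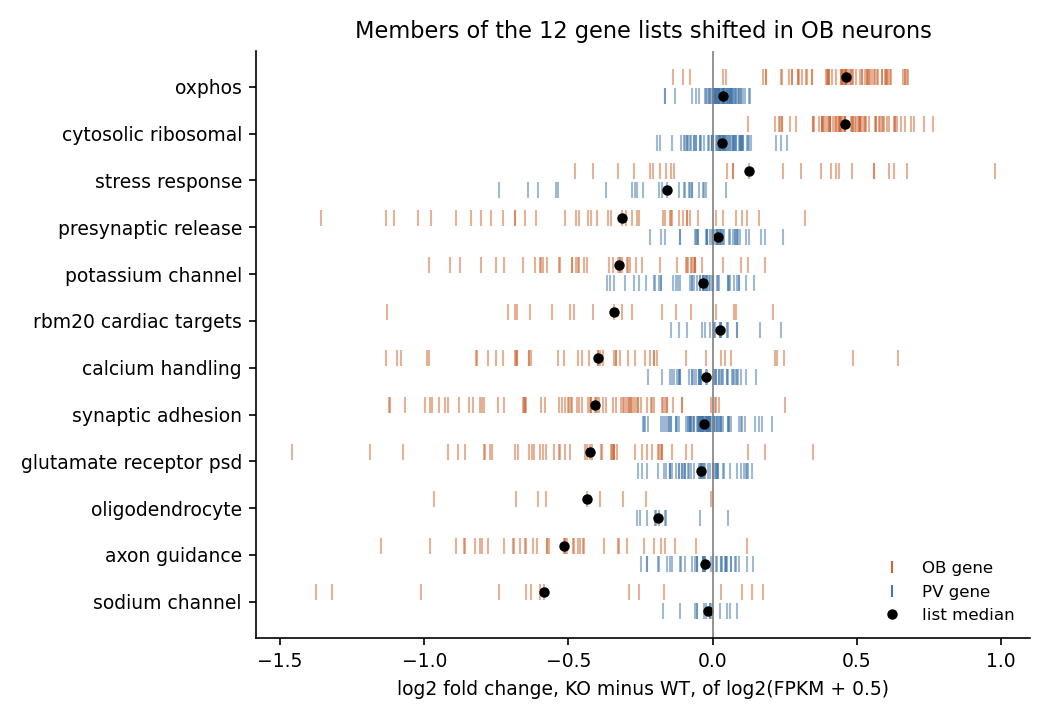
Log2 fold change (KO minus WT) of gene lists in OB and PV, with the median of each list. OB medians reach from -0.58 (sodium channels) to 0.46 (ribosomal and oxidative phosphorylation genes), while PV medians stay between -0.19 and 0.03, and no list passed with an estimated correlation.

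The series title names long pre-mRNAs, so genes spanning at least 100 kb were compared with shorter ones. In OB the 1780 long genes had a median log2 change of -0.31 against -0.03 for 11563 shorter genes, a shift of -0.277 (camera p = 1.20e-12, p = 0.176 with an estimated correlation). Long genes made up 31% of the genes that fell and 1.36% of those that rose, against 13.3% of the genes tested (Fisher exact p = 3.92e-27 and 3.80e-20). Of 170 long genes called, 164 fell, including Ank2, Ank3, Pclo, Dscaml1 and Gabra2, and 6 rose, including Ust. The shift was -0.309 within samples 1 and 2 and -0.264 within the later ones. Across genes, the change followed summed exon length (rho = -0.469) more closely than genomic span (rho = -0.315), and genes are not independent replicates. With genes in 10 bins by summed exon length, the shortest bin (median 622 nt) had a median change of 0.15 and the longest (median 8138 nt) -0.44. In PV the 1771 long genes shifted by 0.00677 and did not pass camera (0.308), and by 0.0101 and 0.0108 within its column batches. This PV shift passed the threshold without PV KO 2 (shift 0.0253) and without PV WT 3 (shift 0.0226), and turned negative without PV WT 1 (shift -0.00542).

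**Figure D3:**
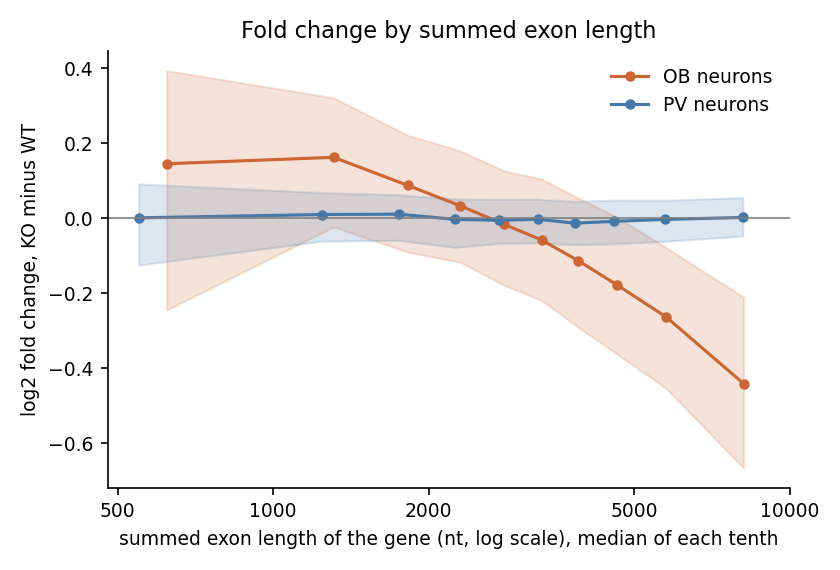
Median log2 fold change (KO minus WT) of tested genes in 10 bins by summed exon length in nt (log axis), for OB and PV, with the range from the lower to the upper quartile of the genes. OB medians go from 0.15 in the shortest bin to -0.44 in the longest, and PV medians stay within -0.01 and 0.01.

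In PV neurons, few genes other than Rbm20 differed between KO and WT. Limma called 5 of 13206 genes: Rbm20 fell, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher. The Y-linked genes were listed at 0 in all 4 WT samples and at 14.6 ± 1.38, 6.39 ± 1.22, 3.17 ± 0.315 and 1.68 ± 0.120 FPKM in KO (SD, n = 4). Xist, which is made by the inactive X chromosome, was at 0.265 to 0.639 FPKM in the WT samples and at most 0.000974 in KO. All 4 KO samples were thus male by these transcripts and all 4 WT samples female, so sex and genotype cannot be told apart in PV, whereas 3 of 5 KO and 4 of 5 WT samples of OB carried Ddx3y. Without sex-linked genes and genes within 10 Mb of Rbm20, limma called 0 genes (479 at p under 0.05), against 495 at p under 0.05 over all genes. WT and KO did not overlap in 2.45% of tested genes, against 2.86% by chance. The genes with the next smallest p did not pass: the heat shock gene Hspa1a (-0.54, adjusted p = 0.119), the X-linked initiation factor Eif2s3x (-0.46, 0.234), the histone gene H2ac19 (-0.61, 0.247), Jph4 (-0.41, 0.376) and Trim17 (-0.35, 0.684). Within column batches 4 and 7 genes were called (451 and 787 at p under 0.05). In the authors' deposited table for PV, 13 genes were called, which included all 5 and also Hspa1a (adjusted p = 1.99e-06), Eif2s3x (0.00437) and H2ac19 (0.0168).

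Shifts of gene lists in PV were small. Stress response genes were lower (median -0.16, 24 of 25 negative, camera adjusted p = 2.96e-05). Of single genes only Hspa1a fell when adjusted over the list alone, and 0 passed limma over all genes. Immediate early genes, which respond to activity, had a median of -0.19 (20 of 24 negative, 0.000154), with 0 members called also when adjusted over the list alone. Oligodendrocyte genes were at -0.19 (9 of 10 negative, 0.000154), potassium channel genes at -0.03 (35 of 49 negative, 0.0397) and oxidative phosphorylation genes at 0.03 (62 of 75 positive, 0.00723), likewise with 0 members called when adjusted over the list alone. Each of these 5 lists had an adjusted p = 0.625 with an estimated correlation, and 0 of 21 lists passed with it or with fry (0 at p under 0.05 in each). The call of the immediate early list was lost without PV WT 4 (0.224) and that of the oligodendrocyte list without PV WT 2 (0.050). Oxidative phosphorylation lost its call without PV KO 3 (0.169), PV WT 2 (0.190) or PV WT 3 (0.596) and with quantile scaling (0.413), and potassium channels without PV KO 2 (0.101), PV KO 3 (0.128), PV WT 2 (0.230) or PV WT 3 (0.246). The number of lists called was 8 without PV KO 1, PV KO 3 or PV KO 4, 11 without PV WT 1 and 2 without PV WT 2, and 4 and 3 within the column batches. All PV lists moved with sex as well as genotype.

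The other PV lists did not pass camera. Those nearest the threshold were astrocyte markers (median -0.10, adjusted p = 0.0803), synaptic adhesion (-0.03, 0.0803), glutamate receptor and postsynaptic density (-0.04, 0.0835), cortical excitatory markers (-0.08, 0.0848) and cytosolic ribosomal genes (0.03, 0.0848). With the replicate number as a block, astrocyte markers (adjusted p = 0.0253) and cortical excitatory markers (adjusted p = 0.0418) passed, both downward. For both the adjusted p = 0.71 with an estimated correlation in the same fit, and adjusted p = 0.625 without the block. The adjusted p was 0.119 for granule and periglomerular markers, 0.179 for presynaptic release, 0.203 for axon guidance and for other cortical interneuron markers, 0.313 for microglial markers and 0.360 for splicing factors. It was 0.403 for calcium handling and for cardiac RBM20 targets, 0.434 for PV interneuron markers, 0.489 for sodium channels and 0.955 for GABA and glycine synapses. PV interneuron markers had a median of 0.02 and a mean of -0.04, and GABA and glycine synapse genes a median of -0.01 and a mean of 0.01. The cardiac RBM20 targets with a mean FPKM of at least 1 lay between -0.14 (Dst) and 0.24 (Pdlim3) in PV, and none passed.

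The KO effects of the neuron types were compared directly over 12221 genes tested in both tables. Limma's interaction contrast called 8 genes, 4 with the higher effect in OB and 4 with the lower, and 2546 at p under 0.05. Ust rose in OB (1.81) and was at 0.13 in PV, and Rbm20 fell further in OB (-3.40 against -1.97), where its WT level was higher. Fam89b (0.53 against -0.25), Ifitm10 (0.52 against -0.22) and Ecsit (0.49 against -0.12) completed the 5 with the smallest p, each with an adjusted p = 0.0421. The count went to 1637 without OB KO 2 and to 13 without OB WT 5 or OB WT 6. It was 5 without PV KO 3, 2 without OB KO 5, OB WT 2 or PV WT 1, and 1 without OB WT 1 or PV KO 2. In limma it was 0 without OB KO 3 (2130 at p under 0.05), OB KO 4 (2007), OB WT 4 (2838), PV KO 1 (2007), PV KO 4 (2223), PV WT 2 (2367), PV WT 3 (2223) or PV WT 4 (1884). Fold changes of the neuron types correlated weakly across genes (r = 0.0848, jackknife SE over samples 0.116, rho = 0.149), and 56.1% of genes had the same sign, against 72.4% of the genes called in OB. With replicate numbers, and in OB shared column numbers, as a block, 849 genes differed. Of 920 genes called in OB and tested in both, 7 differed between the neuron types by this contrast. The median size of the change of these 920 was 0.581 in OB, where they were chosen, and 0.0664 in PV. In simulations the contrast recovered 25.0% of changes of 0.5, so the genes that did not differ were not shown to share an effect. PV effects in this fit cannot be told apart from sex.

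Exon use was compared because the series asks for RBM20-dependent splicing. In OB, diffSplice called 37 of 126042 exon parts, 15 used more and 22 used less in KO, in 32 genes. Exon 3 of Papss1 (chr3:131567502-131567678), which encodes an enzyme that makes the sulfate donor, fell by 2.13 on the log2 scale relative to its gene, from 11.3 ± 3.53 to 3.09 ± 2.53 RPKM (SD, n = 5 each, adjusted p = 8.61e-12). Exon 9 of the myelin gene Mbp (chr18:82575601-82575633) fell by 1.56, exon 6 of Ccdc28a (chr10:18216260-18216282) by 1.41 and exon 4 of Ube2d3 (chr3:135455237-135455300) by 1.17. Both listed pieces of an alternative part of exon 1 of Tmem205 (chr9:21927158-21927263 and chr9:21926335-21927157) rose, by 1.72 and 1.64. An alternative part of exon 9 of the inositol pyrophosphate kinase Ppip5k1 (chr2:121348192-121348466) rose by 1.40, and exon 2 of Usp9x (chrX:13072215-13072325) by 1.18. Very short parts were among the calls, a 4 nt part of exon 1 of Prkcsh (chr9:22003089-22003092, -1.69) and a 5 nt part of exon 2 of the spliceosome gene Prpf31 (chr7:3630743-3630747, 1.26). All positions are mm10. WT and KO did not overlap in 16 of the 37, and in 1.11% of the tested parts against 0.794% by chance. Blank cells, set to the lowest listed value, were held by 13 of the 37. Among these were the Papss1, Prkcsh, Mbp and Ppip5k1 parts and the longer Tmem205 part. Mbp fell as a gene too.

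At an adjusted p under 0.05 without the size threshold there were 104 parts in OB, and 3050 at an unadjusted p under 0.05. The count was 61 without OB KO 2, and 2 when each part was taken as a ratio to its gene (7753 at p under 0.05), a setting in which only the Prkcsh part kept its call among those named. The Ube2d3 exon lost its call without OB KO 2, OB KO 3, OB WT 2, OB WT 3, OB WT 4 or OB WT 5 (adjusted p from 0.0502 to 0.375). The Usp9x exon lost it without OB KO 4, OB KO 5, OB WT 1, OB WT 3, OB WT 4 or OB WT 5 (0.0690 to 0.290). Here OB WT numbers are those of the exon table. Parts of long genes were 21.6% of the calls and 22.8% of the parts tested (Fisher exact p = 1). The replicate number as a block gave 55 calls, and the column batch as a covariate 60, which held all 37. In the authors' deposited table of OB exons, 1202 of 131225 parts had an unadjusted p under 0.01 and 0 passed after Benjamini-Hochberg adjustment. Of the 17 called parts that could be matched to the authors' deposited table, all 17 had the same sign and 6 had a p under 0.01 there. The Papss1 exon had p = 0.0748 in the authors' deposited table.

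In PV, diffSplice called 8 of 130312 exon parts, 3 used more and 5 used less in KO, in 7 genes. WT and KO did not overlap in 5 of the 8, and in 4.23% of the tested parts against 2.86% by chance. Blank cells, set to the lowest listed value, were held by 4 of the 8, among them the Rabl2 part named below. Exon 1 of the vesicle fusion gene Vamp2 (chr11:69088509-69088627) fell by 1.60 relative to its gene, from 10.2 ± 3.68 to 2.80 ± 0.732 RPKM (SD, n = 4 each, adjusted p = 4.45e-06). Exon 2 of Ecsit (chr9:22084013-22084198), a mitochondrial assembly factor, rose by 2.22, from 8.85 ± 9.31 to 21.7 ± 6.99 RPKM, carried by PV WT 1 and PV WT 2: the rise was 3.85 within samples 1 and 2 and 0.58 within samples 3 and 4. A part of exon 6 of Rabl2 (chr15:89584008-89584278) fell by 1.05 and exon 5 of the two-pore channel gene Tpcn1 (chr5:120556472-120556585) by 1.01. In OB the same Ecsit exon fell by 3.42 (adjusted p = 6.34e-18), with overlap between genotypes. Exon 5 of Fam204a (chr19:60220330-60220360), chosen after its values were seen, fell in both tables, by 1.62 in OB and 1.47 in PV, with overlap. It lies 6.35 Mb from Rbm20, so linkage to the targeted locus was not told apart from an effect of RBM20 loss. All positions are mm10.

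At an adjusted p under 0.05 without the size threshold there were 439 parts in PV, and 5273 at an unadjusted p under 0.05. First exons made up 62.9% of the 439 and 6.0% of the parts tested (Fisher exact p = 1.0e-219), and 272 of these 276 were lower in KO. This test treats exon parts as independent, although all come from the same 8 samples. Over samples, the median level of first exons relative to their genes gave an exact permutation p = 0.0571. The count of 8 was 16 without PV KO 2, 19 without PV WT 3 and 13 without PV WT 4, 8 with the column batch as a covariate, and 0 by limma when each part was taken as a ratio to its gene (9133 at p under 0.05). The Ecsit call was lost without both samples numbered 1 (adjusted p = 0.174). The Rabl2 call was lost without PV KO 1, PV KO 2, PV WT 2 or PV WT 4, and the Tpcn1 call without PV KO 1, PV KO 3, PV KO 4, PV WT 1 or PV WT 2, where each relative change fell under the size threshold at adjusted p from 0.00385 to 0.0431. PV calls cannot be told apart from sex. In the authors' deposited table of PV exons, 1329 of 132990 parts had an unadjusted p under 0.01 and 0 passed after Benjamini-Hochberg adjustment. All 5 called parts matched to the authors' deposited table had the same sign, and 1 had a p under 0.01 there.

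**Figure D4:**
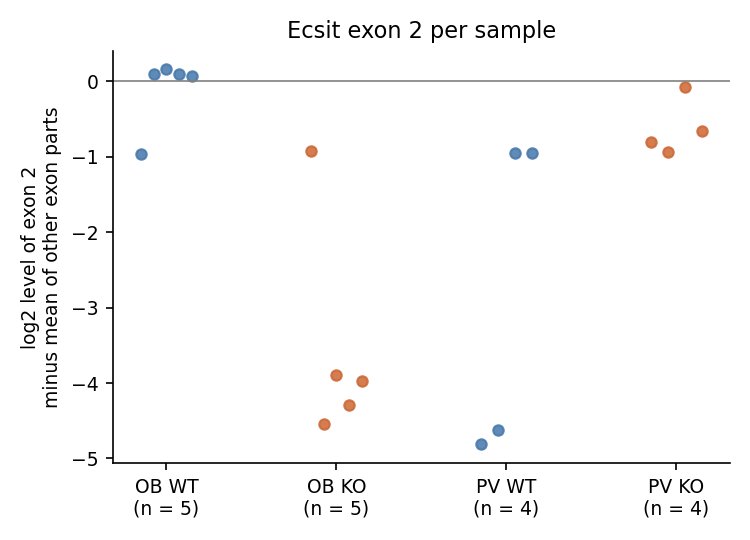
Log2 ratio of Ecsit exon 2 to its gene in each of the 18 samples, by neuron type and genotype. Samples lie near 0 (5), near -1 (7) or below -3.5 (6), with 0 between.

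Exons of the genes that RBM20 splices in heart were looked at separately. In OB, 317 exon parts of 15 such genes were tested and 0 passed in diffSplice. The smallest p was that of exon 16 of Pdlim5 (chr3:142249330-142249510, mm10; relative change -1.06, adjusted p = 0.334). In PV, 531 parts of 17 genes were tested. Exon 4 of the tropomyosin gene Tpm1 (chr9:67043578-67043871, mm10) was lower by 0.50 (adjusted p = 0.0298), below the size threshold, with overlap between genotypes. Parts of the calcium release channel Ryr2 and of Cacna1c were tested in PV and did not pass.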

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

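The tests on summed exon length, on the column batches of OB, on the placement of calls along chromosomes, on effects shared by the neuron types, on the ratio of 5-prime to 3-prime levels in PV and on the Ecsit variant were chosen only after the result was seen. A sample far from the others of its group was found in 15 of 244 groups examined, where chance flags about 1 in 20 groups, or 12.2 here.

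OB KO 2 stood apart from the other OB KO samples in 7 genes, on the WT side in each: Ank3 at 5.94 FPKM (others 2.51 to 3.30), Ank2 at 6.60 (3.28 to 4.07), Mycbp2 at 3.40 (1.31 to 1.80), Sema4d at 5.40 (3.68 to 4.06), Fhod3 at 11.2 (5.26 to 6.41), Cox5a at 790 (960 to 1023) and Manf at 26.5 (35.8 to 39.0). Rec114 was at 1.57 FPKM in OB WT 4, far from the other WT samples (0.824 to 1.02). Pvalb was at 6.47 in OB WT 2, far below the others (10.9 to 12.5). OB KO 1 had 19489 genes above 0, far from the other OB KO samples (21434 to 21792). In PV, Pvalb was far below the others of its genotype in both samples numbered 1, at 239 FPKM in PV KO 1 (others 1189 to 1214) and 226 in PV WT 1 (1123 to 1242). Enah was at 24.9 in PV WT 3 (others 21.5 to 22), Tpm1 at 188 in PV WT 4 (172 to 175) and Gad2 at 104 in PV KO 2 (134 to 138), each far from the rest of its group.

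The KO effect differed between OB and PV in 8 genes by the test of the difference itself. The differences (OB minus PV) were 0.78 for Fam89b, 1.68 for Ust, -1.43 for Rbm20, 0.74 for Ifitm10 and 0.62 for Ecsit.

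In OB KO, long transcripts were low and short ones high. Against genes matched on summed exon length, the shift of genes spanning 100 kb or more was -0.114 (SE 0.0140, 1667 genes) instead of -0.277, so exon length may account for much of it and the remainder was not explained. Less 5-prime coverage in KO could not be told: the ratio of 5-prime to 3-prime exon levels differed by -0.0301 between genotypes (SD between samples 0.0563, exact permutation p = 0.452). The column batch is excluded as the sole cause, since the shift was -0.264 within the later samples and -0.309 in samples 1 and 2. A direct effect of RBM20 loss on long genes was not told apart from a difference between libraries that follows transcript length.

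In PV KO, first exons were low relative to their genes. Lower 5-prime coverage of the whole KO libraries could not be told: genes without any exon past the threshold showed the shift too (median -0.0874, SE 0.00275 over 6885 genes), but over samples the index gave an exact permutation p = 0.0571, and pair 3 ran the other way (-1.24 in KO, -1.31 in WT). The ratio of 5-prime to 3-prime exon levels was -0.486 in KO and -0.474 in WT (exact permutation p = 0.6). The column batch could not be told: the difference was -0.0422 within samples 3 and 4 and -0.169 within samples 1 and 2. Sex could not be told either, since Y-linked transcripts were present in 4 of 4 KO samples and in no WT sample.

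In OB, exon calls gathered on chromosome 9, with Ubl5, Tmem205, Prkcsh and Ecsit within 5 Mb (chr9:18292266-23292266, mm10). As many genes in a window were found in 0.7% of 1000 shuffles. This test was chosen after the grouping was seen and treated every gene as equally likely to hold a call, so chance placement is not excluded. Whether a KO effect of the same size was present in both neuron types could not be told. All 6 parts tested in both tables differed by more than 2 SE, such as Prkcsh (-1.69 in OB, 0.41 in PV) and Tmem205 (1.72 and -0.07), and 5 had opposite signs. These parts were chosen by their OB calls, which favours larger effects in OB, and the criterion was set after the effects were seen. Sex could also have offset an effect in PV. A strain variant in the segment may be involved but could not be told: over 8 PV samples the Ecsit and Prkcsh levels correlated at r = 0.601 (exact permutation p = 0.109). A variant of Ecsit that segregates within the genotypes could not be told either, although all 18 samples lay at 3 levels of exon 2, because the bounds of the levels were set from the values.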

How the results depend on the processing

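The settings on the column batch, the exon-length trend, listed or blank exon cells, the pair of samples numbered 1, the OB column numbers as a block, and estimated correlation for long genes are tests chosen only after the result was seen. No named gene or exon that had passed changed direction under any setting, nor did a called list by its test. The mean of the PV oxidative phosphorylation list, however, went from 0.03 to -0.000705 without PV WT 3, where it did not pass. Named genes that had not passed were not followed across settings. Outside leave-one-out, 229 of 970 values of called OB genes, 15 of 167 of OB lists, 12 of 113 of OB exons, 0 of 53 of PV genes by limma, 12 of 55 of PV lists, 10 of 49 of PV exons and 9 of 34 of the difference no longer passed. In leave-one-out these were 435 of 610, 2 of 120, 12 of 100, 0 of 40, 9 of 40, 9 of 32 and 60 of 90. No limit from counting was set, since the steps of FPKM values gave relative depth only.

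The OB gene count (970) moved to 7 without a filter, 472 with quantile scaling, 3566 with sample weights, 493 at a fold change of at least 1.5, 3982 with the column batch as a covariate, 24 without OB WT 1 and 2, 3276 in the later samples only, 1 in samples 1 and 2 only (2970 at p under 0.05) and 373 with the exon-length trend removed. Leaving out replicates gave 4 to 3400. The OB list count (12) was 0 with camera and an estimated correlation (2 at p under 0.05). The OB shift of long genes kept its value of -0.277 with an estimated correlation but no longer passed. The OB exon count (37) was 81 with pseudocount 0.1, 2 as ratios to the gene, 104 without a minimum change, 24 with parts listed in every sample, 107 with blanks at 0, 60 with the column batch, and 29 to 61 in leave-one-out.

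The PV gene count (5) was 3 at a mean FPKM of at least 2 and 0 by limma without sex-linked genes and genes near Rbm20 (479 at p under 0.05). The PV list count (5) was 9 without a filter, 9 without both samples numbered 1, 0 with camera and an estimated correlation or with fry (0 at p under 0.05), and 2 to 11 in leave-one-out. The PV shift of long genes (0.00677) was reversed to -0.0143 without both samples numbered 1, and ranged from -0.00542 to 0.0253 in leave-one-out. The PV exon count (8) was 24 with pseudocount 0.1, 5 with pseudocount 1, 0 by limma as ratios to the gene (9133 at p under 0.05), 439 without a minimum change, 4 with parts listed in every sample, 155 with blanks at 0, and 6 to 19 in leave-one-out. The count of genes that differ between neuron types (8) was 5 without a filter, 5 at a mean FPKM of at least 2, 2 with quantile scaling, and 0 (by limma; 2130 at p under 0.05 without OB KO 3) to 1637 in leave-one-out. The cause was not tested, except that subsets hold fewer samples and a threshold on size or level fewer candidates.

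With the replicate number as a block, the PV counts were 5 genes, 7 lists and 8 exon parts, the PV Rbm20 change was -1.97 and the PV shift of long genes 0.00677. Astrocyte and cortical excitatory markers passed only with the block (adjusted p = 0.0253 and 0.0418), and it changed no other call of a list or named result. The OB exon count was 55 with the block. The WT columns of the OB gene table carry no sample number, so a replicate block was fitted on the column numbers that both genotypes share. It gave 1531 OB genes, 13 lists, an Rbm20 change of -3.47, a shift of long genes of -0.269 and 849 genes that differ between neuron types. The cause was not tested. Sex as a covariate was not run in PV, where it follows genotype, nor for OB exons, where gene and exon columns are numbered differently.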

Other observations

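The tests on gene families, on gene placement and on splits that part shared OB column numbers were chosen only after the result was seen. In OB KO, further gene families shifted by camera, most members not passing singly except in ATP synthase. Of 77 mitochondrial ribosomal protein genes, 14 rose and 74 had positive changes (median 0.32, camera adjusted p = 1.27e-18, adjusted p = 0.219 with an estimated correlation). Of 17 ATP synthase genes, 10 rose (median 0.48, 3.06e-11, adjusted p = 0.219 with an estimated correlation). The oxidative phosphorylation list already holds ATP synthase genes such as Atp5j2, so this family is not separate support. Of 36 proteasome genes, which degrade tagged proteins, 5 rose (median 0.28, 1.98e-10, adjusted p = 0.219 with an estimated correlation). Of 52 translation initiation factor genes, 4 rose and 1 fell (median 0.14, 0.00455, adjusted p = 0.219 with an estimated correlation). Kinesin genes, which code for motors along microtubules, were lower: all 18 were negative and 1 fell (median -0.67, 1.15e-05, adjusted p = 0.308 with an estimated correlation). Of these families ATP synthase had the shortest transcripts and kinesin the longest (median summed exon length 907 nt for ATP synthase and 6386 nt for kinesin genes), and OB changes followed that length (rho = -0.469), so these shifts were not told apart from it. OB KO samples also had fewer genes above 0 (19489 to 21792 against 23097 to 24952) and lower oligodendrocyte transcripts (median -0.44).

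Some families changed sign with quantile scaling. Vacuolar ATPase genes, with 4 of 20 higher, had a median of 0.18 and of -0.06 after quantile scaling. Zinc finger genes, with 6 of 319 lower, had a median of -0.11 and of 0.07 after quantile scaling. Protocadherin genes had a median of -0.18 and of 0.02 after quantile scaling. In PV the medians of all these families lay between -0.01 and 0.06. There proteasome (camera adjusted p = 0.00447), ATP synthase (0.00802), initiation factor (0.0124) and Rab trafficking genes (0.0151) passed upward, each with an adjusted p = 0.642 with an estimated correlation. The 1 initiation factor gene called singly in PV was the Y-linked Eif2s3y, which follows sex. Rab trafficking genes also passed camera in OB (median 0.07, adjusted p = 0.0360, adjusted p = 0.219 with an estimated correlation).

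Of 3276 genes called within the later OB samples, 91.2% had the same sign in samples 1 and 2, and fold changes of the batches correlated at r = 0.525 across genes. Genes with an official name that changed at least 2-fold were not grouped beyond chance in a scan of 5 Mb windows, which ignored direction. The fullest window, with Akap12, Zc3h12d, Ust and Sash1 on chromosome 10, was matched in 13% of 1000 shuffles. Of these, Zc3h12d (1.55) and Ust (1.81) rose, and Akap12 (-1.21) and Sash1 (-1.04) fell. Adat2, which also rose (1.12), starts outside the window at chr10:13552893 (mm10). The scan therefore cannot exclude a grouping of rising genes on this chromosome. With gene models lacking a name included, 10 models fell within chr8:117207942-117214690 (mm10), as many as in 0% of 1000 shuffles. All 10 are short, such as chr8:117207942-117207968, and were lower in KO (log2 -1.16 to -1.63). The shuffles counted each as a separate gene, so they cannot tell a grouping of genes from pieces of the same locus.

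Other splits of the samples were compared with the real grouping. With every split counted alike and the real one included, 2 of 100 were as large for the OB gene count (970, highest other 1803), 3 of 100 for the OB exon count (37, highest other 39), 3 of 100 for the OB shift of long genes (0.277, highest other 0.325), 16 of 100 for the OB lists (12, highest other 17) and 3 of 100 for the genes that differ between neuron types (8, highest other 128). Those splits ignore that OB gene columns sharing a number deviate together, as do OB exon columns for 4 of 5 numbers. Only 16 OB gene splits part all 4 shared numbers and only 16 OB exon splits all 5, too few for a share under 5%. Among them the highest other was 1 for the gene count, 0.196 for long genes, 14 for lists (12 in the real one) and 11 for exons (37 in the real one). The OB split with 1803 exchanged OB KO 2 and OB WT 4, and the OB exon split with 39 mostly followed samples 1 and 2. In PV, 2 of 35 were as large for the gene count (5, highest other 452), 5 of 35 for the exon count (8, highest other 11), 25 of 35 for the lists (5, highest other 13) and 30 of 35 for the long genes (0.00677, highest other 0.0567). The largest PV gene and exon splits set samples 1 and 2 against 3 and 4, the column batch. Only 8 PV splits part all pairs, too few for a share under 5%. Among them the highest other was 0 for the gene count by limma (5 in the real one), 6 for exons (8), 11 for lists (5) and 0.0567 for long genes (0.00677).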
